A study of Mus musculus with 14 samples.

How the data were processed

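Hepatic transcript levels were measured on 14 Affymetrix whole-transcript arrays, 1 array per mouse. Per the labels, 7 arrays carried RNA from wild-type (WT) mice and 7 carried RNA from mice with the K289R substitution in LRH-1, the nuclear receptor encoded by Nr5a2. Each array was described as a biological replicate. The labels gave an age of 17 to 19 weeks, feeding ad libitum and a harvest at 7 am. Total RNA was extracted with Trizol and 100 ng was amplified with a whole-transcript kit before biotin labelling, per the labels' protocols. Sex, litter, cage, RNA batch, hybridisation batch and scan date were not given in the sources used here.

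The deposited values were probe set intensities on a linear scale, summarised by the authors with Affymetrix Expression Console, per the submitters' processing notes. The version of that program, the background correction, the summarisation method and the genome build were not given in the sources used here. The deposited intensities ran from 2.104 to 12782, and the medians of the 14 arrays lay between 39.19 and 43.31. The quartiles of the arrays were close to each other but not identical, and whether the arrays had been scaled to each other stays unknown. Values from an array have no read depth, and the number of arrays limits the precision. Each analysis used log2(intensity + 1), a scale on which the change of dim genes is understated.

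Of 35556 probe sets, 21456 were paired with 1 gene symbol by the platform annotation, 2376 were paired with several symbols and were left out, and 11724 were not listed there and stayed unnamed. Symbols were updated through the Entrez identifier in the gene table of assembly GRCm38.p6. This matched 21277 probe sets and replaced 2 symbols. That table also gave the genes that neighbour Nr5a2, and no coordinate is reported because the build behind the deposited values is unknown. The 19237 genes were each represented by the probe set with the highest mean over all 14 arrays, a choice that concerned 1343 genes with more than 1 probe set. Genes with no probe set of their own name were not analysed here. Near-identical gene copies can hybridise to the same probes, so single members of the ribosomal protein, histone, Cyp2c, Ugt and Selenbp families are uncertain.

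The K289R and WT livers were compared with limma 3.58.1 in R 4.3.3. The model held genotype alone, the prior variance followed an intensity trend, tests were 2-sided and p was adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Differences are given as K289R minus WT in log2 units with the standard error (SE) of the moderated model. Group levels are given as mean ± SD of 7 arrays. The procedure was tested on simulated data with the means and spread of these 19237 genes and 200 changed genes. The changed genes were drawn only from the genes with a mean above the median of all genes. It called 22% of the genes changed by a fold of 1.2, 92% of those changed by a fold of 1.5 and 100% of those changed by a fold of 2 or 3, together with 3 unchanged genes. These rates describe the simulated data and need not hold for the real arrays. In the real data 3678 genes passed, and arrays of the same genotype formed sets, as described below. The rates cover brighter genes only, and no rate was obtained for dim genes.

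Before the data were examined, 34 gene lists were fixed for liver metabolism, nuclear receptor targets, harvest time, sex, and cells other than hepatocytes. They named 511 genes, of which 442 were measured. The reverse cholesterol transport list rests on what is known of the published study and is not independent of it. Lists were tested with camera at a preset correlation between genes of 0.01, with an estimated correlation and with fry as alternatives. Camera compares a list with all other genes. The fry p tests whether the members move, on balance, one way, and its mixed p tests for change in either direction. Nr5a2 was tested by an exact permutation test over all 3432 assignments of the arrays. Genes within 20 Mb of Nr5a2 were compared with other genes by a 2-sided Fisher's exact test.

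The rule for naming genes was also fixed then. It took Nr5a2, the 12 genes with the largest change in each direction among those past the threshold (filled up to 8 by the smallest p had fewer passed), up to 4 passing members of each list or else the 2 with the smallest p, 8 genes of cholesterol and bile acid handling whatever their result, and up to 6 genes near Nr5a2. Other genes named in the text were chosen after their values were seen. Alternatives fixed then were quantile normalization, median centring, the replicate number as a block, array weights, 1 surrogate variable by the iteratively reweighted method of the sva package, written out in R, other variance priors, filters on dim genes, the mean of probe sets, a Welch test per gene, other thresholds and leaving out each array in turn. Alternatives chosen after seeing the data were no pseudocount, the interquartile range of each array as a covariate, leaving out the 2 K289R arrays with the lowest interquartile range, an exact permutation test of the mean of each list, and several treatments of the sets formed by replicates 1 to 4 and 5 to 7 of each genotype. These were a set term in the model, the comparison within each set, an interaction of genotype and set, the 4 sets as random blocks by duplicateCorrelation, and permutation of list means within the sets over 1400 assignments. Figures were drawn with matplotlib 3.10.9.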

Results

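Liver RNA of 7 WT and 7 K289R mice was profiled to ask how the loss of a SUMO acceptor lysine in LRH-1 alters hepatic transcripts. LRH-1 is a nuclear receptor that acts on bile acid and cholesterol genes. Values were obtained for 19237 named genes, with no filter on detection in the main comparison, so unexpressed genes are among them. The median correlation between arrays was 0.989 within WT, 0.988 within K289R and 0.983 between the genotypes. Olfactory receptor genes, which stand here for unexpressed genes, had medians of 3.34 to 3.52 in log2 units over the arrays. Transcripts of the Y-linked genes Eif2s3y, at 6.96 to 8.12, and Uty, at 6.21 to 7.37, were above that level on each of the 14 arrays. Xist lay between 3.33 and 3.67.

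The arrays of both genotypes occupied separate areas of a principal component plot whose axes held 42.55% and 19.09% of the variance. The interquartile range of log2 values differed between arrays, from 2.36 to 2.83 in WT and from 2.28 to 2.70 in K289R livers, a difference between genotypes with an exact permutation p of 0.298. K289R replicates 6 and 7 had the lowest interquartile ranges and the highest scores on the first component, 30.205 and 36.575. Within each genotype the arrays fell into sets that the labels do not name. Between replicates 5 to 7 and replicates 1 to 4, 57 genes passed limma's adjusted p of 0.05 in WT and 1754 in K289R livers, the most of all 35 divisions into 3 and 4 arrays, of which the next gave 2 and 19. In K289R livers replicates 5 to 7 also had lower interquartile ranges (2.28 to 2.49) than replicates 1 to 4 (2.61 to 2.70). In WT livers the ranges of the sets overlapped. In what follows, calls were also tested with the 4 sets (2 of each genotype) as random blocks. That fit uses 1 correlation for all genes (0.178) and counts arrays, although genotype varies only between sets. A call that it keeps can therefore still be overstated where the sets differ much.

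**Figure D1:**
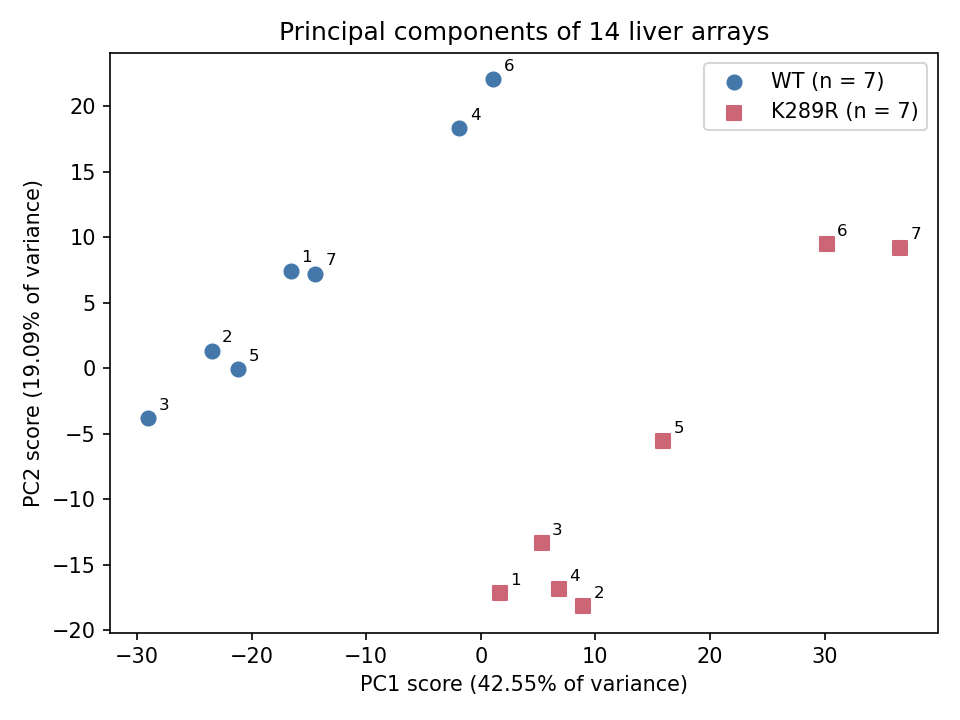
Scores of the 14 arrays on the first (x axis, 42.55% of variance) and second (y axis, 19.09%) principal component of log2 values of 19237 genes, with circles for WT, squares for K289R and the replicate number beside each point. The genotypes do not mix, and K289R replicates 6 and 7 lie farthest to the right.

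The largest increases in K289R livers were those of Ctse and Asns. Ctse, which encodes the aspartic protease cathepsin E, rose from 4.72 ± 0.27 to 9.30 ± 0.21 (log2, mean ± SD, n = 7 each), a fold of 23.9. Asns, which encodes asparagine synthetase, rose from 6.32 ± 0.89 to 10.85 ± 0.28, a fold of 23.1. Each of the 7 K289R arrays lay above each WT array for both genes. At the other end, the small nucleolar RNA Snord82 fell by 2.74 ± 0.21 (log2, SE) and Atp5md, a subunit of ATP synthase, fell by 2.27 ± 0.11.

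Further genes with large increases were Igfbp1, which encodes an insulin-like growth factor binding protein (1.62 ± 0.37, log2 ± SE), Osbpl3, an oxysterol-binding protein relative (1.51 ± 0.14), the steroid hydroxylase gene Cyp17a1 (1.48 ± 0.23), the long noncoding RNA Meg3 (1.41 ± 0.14), Slc35f2 (1.33 ± 0.12), and Csad, which makes hypotaurine for taurine synthesis (1.24 ± 0.14). Gldn rose by 1.19 ± 0.17, Emp2 by 1.07 ± 0.08, Wfdc2 by 1.07 ± 0.15, and Selenbp2 by a fold of 2.30. The levels of Igfbp1 were spread widely in K289R livers, from 6.42 to 9.65, and 5 of 7 arrays lay above each WT array. Its difference was 2.07 among replicates 1 to 4 (adjusted p = 0.000509) and 1.03 among replicates 5 to 7 (adjusted p = 0.134). Asns lay at 6.71 to 7.33 on WT replicates 1 to 4 and at 5.27 to 5.49 on WT replicates 5 to 7, so that its rise was 3.83 in the former set and 5.47 in the latter (adjusted p of the interaction = 0.00677).

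The genes with further large decreases differ in function. The splicing factor gene Zcrb1 fell by 2.25 ± 0.11 (log2, SE), the proteasome subunit gene Psmb5 by 1.69 ± 0.07, the ribosomal protein gene Rpl12 by 1.59 ± 0.06, the complex I assembly gene Tmem126a by 1.64 ± 0.11 and the vesicle fusion gene Vamp7 by 1.58 ± 0.13. Plscr2, Fabp7, H4c4, Snord73b and Rnase2a fell by 1.71 to 2.03, and for Rnase2a the K289R mean of 3.28 was no higher than that of the olfactory receptor genes, so that its fall is a lower bound. Zcrb1 differed by -1.97 among replicates 1 to 4 and by -2.61 among replicates 5 to 7 (adjusted p of the interaction = 0.0158). For Rnase2a these differences were -2.59 and -0.775 (adjusted p of the interaction = 0.0086). For Snord73b they were -1.10 and -2.51 (adjusted p of the interaction = 0.353). The 3 probe sets of Atp5md fell alike, but whether they share probes was not examined, so their agreement is not separate support. Of the 6 probe sets of Rpl12, 5 fell and the remaining one, with a mean of 5.15, had a difference of 0.02. Which of them measures Rpl12 itself rather than a near-identical copy was not examined.

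In total, 3678 of 19237 genes (19.12%) passed limma's adjusted p of 0.05, 1610 higher and 2068 lower in K289R livers. With quantile normalization the split turned, with 2406 higher and 2028 lower genes, and median centring gave 1102 and 1905. The median of the absolute log2 change of called genes was 0.36, a fold of 1.28. A fold of at least 2 was reached by 13 higher and 108 lower genes. For 1451 genes the values of both genotypes did not overlap, where chance gives 0.0583% of genes. Among replicates 1 to 4 alone 2710 genes passed, and among replicates 5 to 7 alone 1762. The interaction of genotype and set passed an adjusted p of 0.05 for 22 genes, 7 of them among the 3678. The sets are small, so further interactions may have been missed. Of the 3678 genes, 2176 passed with sets as random blocks.

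Nr5a2 itself did not differ, at 8.77 ± 0.09 in WT and 8.76 ± 0.22 in K289R livers (exact permutation p = 0.981, 2-sided). The difference had a 95% confidence interval of -0.18 to 0.18. The substitution changes 1 residue, so this level does not test the genotype labels. The difference was 0.12 among replicates 1 to 4 (exact permutation p = 0.114) and -0.17 among replicates 5 to 7 (exact permutation p = 0.3).

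Of the 11 measured LRH-1 target genes, 6 rose, 1 fell and 4 did not pass. The counts were the same when p was adjusted over the list alone. Besides Cyp17a1, the risers were Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis (0.62 ± 0.07, adjusted p = 3.68e-06), Nr0b2, which encodes the corepressor SHP (0.61 ± 0.16, adjusted p = 0.00861), the apolipoprotein genes Apom (0.52 ± 0.08) and Apoa1 (0.18 ± 0.04), and the transporter gene Abcc3 (0.34 ± 0.11, adjusted p = 0.0297, and 0.0677 with median centring, the call being lost in 7 of 14 fits that left out 1 array). Abcg8, which encodes one partner of the sterol exporter, fell by 0.37 ± 0.10 (adjusted p = 0.0104). Its partner Abcg5 differed by 0.02 ± 0.10 (adjusted p = 0.883). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.19 ± 0.16 (adjusted p = 0.463). The list as a whole had a camera adjusted p of 0.0708, and adjusted p = 0.979 with an estimated correlation. The fry adjusted p was 0.00145. Cyp8b1, Cyp17a1, Apom and Apoa1 kept their calls with sets as random blocks, and Nr0b2 (adjusted p = 0.0625), Abcc3 (0.122) and Abcg8 (0.0643) lost theirs. Among replicates 1 to 4 the list passed with camera (adjusted p = 0.00984, against adjusted p = 0.458 with an estimated correlation), and among replicates 5 to 7 it did not (adjusted p = 0.169).

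**Figure D2:**
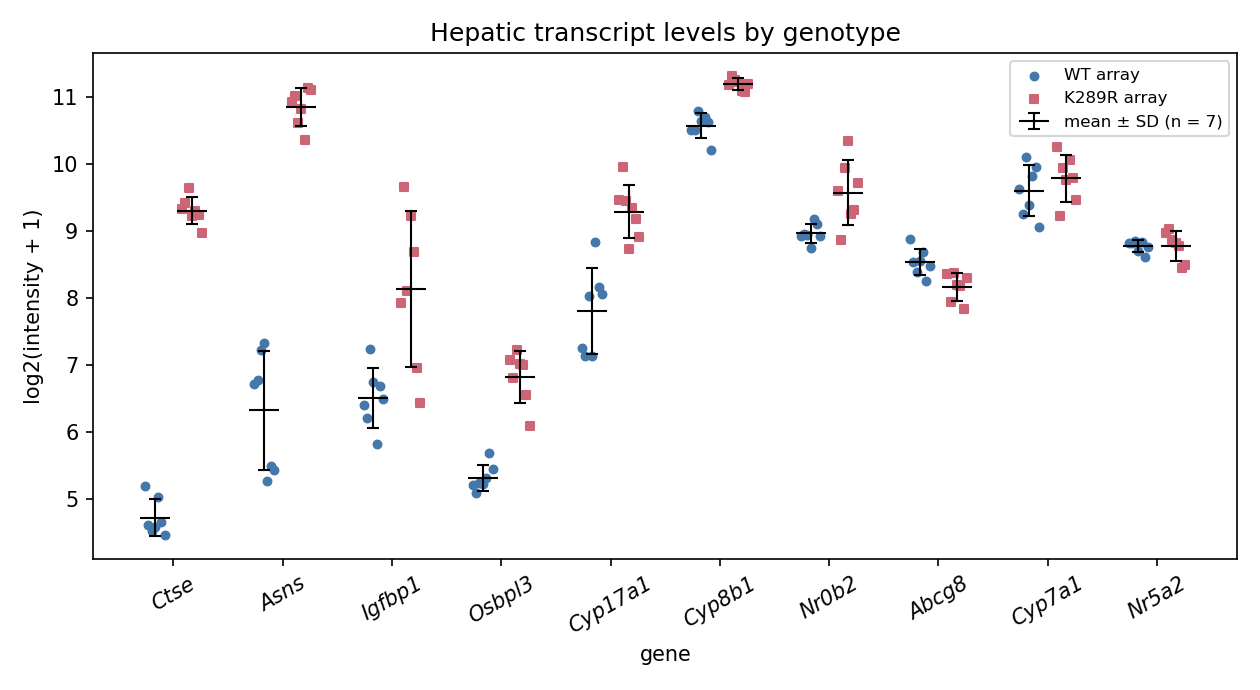
Levels of 10 genes on each array as log2(intensity + 1) (y axis), with circles for WT arrays, squares for K289R arrays, and black bars for the mean ± SD of 7 arrays. The groups are far apart for Ctse and Asns, and overlap for Cyp7a1 and Nr5a2.

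In the reverse cholesterol transport list, chosen with knowledge of the study, 5 of 18 measured genes rose and 1 fell. Adjusted over the list alone, 6 rose and 1 fell. The risers were Lcat, which esterifies cholesterol on high-density lipoprotein (0.33 ± 0.06), Nceh1 (0.42 ± 0.10), Npc1 (0.29 ± 0.08), Lrp1 (0.22 ± 0.07) and Apoa1. The lipoprotein receptor gene Scarb1 (0.02 ± 0.07), the cholesterol efflux transporter gene Abca1 (0.13 ± 0.07) and Apoe (0.06 ± 0.03) did not pass. Abca1 passed with quantile normalization, with an adjusted p of 0.0404. The list had a camera adjusted p of 0.505, adjusted p = 0.979 with an estimated correlation, and a fry adjusted p of 0.0323. An exact permutation test of its mean gave an adjusted p of 0.166. Among 14 LXR target genes 2 rose and 2 fell, also when adjusted over the list alone, with Mylip higher (0.26 ± 0.08, a call lost in 4 of 14 fits that left out 1 array) and Smpdl3a lower (-0.26 ± 0.07). Lcat, Nceh1 and Apoa1 kept their calls with sets as random blocks, and Npc1 (adjusted p = 0.062), Lrp1 (0.126) and all 4 LXR target genes lost theirs.

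Bile acid genes moved both ways. In the synthesis list, 4 of 15 rose and 3 fell, and 5 rose and 3 fell when adjusted over the list alone. Cyp8b1 and Cyp27a1, the sterol 27-hydroxylase (0.28 ± 0.04), were higher, while Cyp2c70, which makes muricholic acids in mice, fell by 0.85 ± 0.09 and Amacr, which acts on the side chain, fell by 0.47 ± 0.06. Among 13 transport genes 1 rose and 3 fell (2 and 3 when adjusted over the list alone), with the uptake carrier genes Slco1b2 (-0.55 ± 0.08) and Slco1a4 (-0.56 ± 0.19) lower. The call of Slco1a4 was lost in 7 of 14 fits that left out 1 array, and that of Abcc2, the third gene that fell (-0.17 ± 0.06), in 9 of 14. Of 20 cholesterol synthesis genes 3 rose and 1 fell, the same as when adjusted over the list alone. Pmvk (0.49 ± 0.09) and Fdps (0.34 ± 0.08), of the mevalonate pathway, rose, and the cholesterol carrier gene Stard4 fell by 0.34 ± 0.08. Under the model with random blocks, 3 synthesis genes rose and 3 fell, Slco1b2 was the 1 transport gene that passed, and 2 cholesterol genes rose and 1 fell.

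Genes of fuel metabolism were divided as well. In the glucose list 5 of 15 rose and 4 fell, and 6 rose and 5 fell when adjusted over the list alone. Pck1, which encodes a gluconeogenic enzyme, rose by 0.96 ± 0.25, whereas Fbp1 fell by 0.28 ± 0.05, Ugp2 by 0.42 ± 0.08 and the fructokinase gene Khk by 0.40 ± 0.09. In the lipogenesis list 3 of 20 rose and 4 fell, with no difference when adjusted over the list alone. The carbohydrate-sensing factor gene Mlxipl rose (0.28 ± 0.06), and Me1 (-0.65 ± 0.13) and Gpam (-0.53 ± 0.13) fell. In the fatty acid oxidation list 3 of 20 rose and 3 fell, against 3 and 4 when adjusted over the list alone. Ppara rose by 0.48 ± 0.07 and the hormone gene Fgf21 by 0.40 ± 0.10, while Fabp1 fell by 0.26 ± 0.07. The fatty acid oxidation list went up among replicates 1 to 4 (camera adjusted p = 0.00227, against adjusted p = 0.668 with an estimated correlation) and down among replicates 5 to 7 (camera adjusted p = 0.00158, against adjusted p = 0.839 with an estimated correlation). Random blocks for the sets left 1 glucose gene that rose and 3 that fell, 2 lipogenesis genes that rose and 2 that fell, and 2 oxidation genes that rose and 1 that fell. Pck1 lost its call (adjusted p = 0.0623).

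One-carbon and methionine genes were higher in 4 of 14 cases and lower in none, over all genes and adjusted over the list alone. Cth, which makes cysteine from cystathionine, rose by 0.44 ± 0.06, Pemt, which methylates phosphatidylethanolamine, by 0.38 ± 0.07, Sardh by 0.33 ± 0.07 and Ahcy by 0.26 ± 0.04. The camera adjusted p was 0.353, with adjusted p = 0.979 with an estimated correlation, and the fry adjusted p was 0.00502. In the list of endoplasmic reticulum stress and amino acid response, 2 of 15 genes rose and 3 fell, and as many when adjusted over the list alone. The members that moved differ in function: the amino acid response genes Asns and Chac1 (0.39 ± 0.10) rose, and the chaperone genes Dnajb9 (-0.97 ± 0.15) and Hspa5 (-0.47 ± 0.12) fell. Atf4, which encodes a regulator of Asns, differed by -0.12 ± 0.07 (adjusted p = 0.249). The 4 one-carbon genes kept their calls with sets as random blocks, and Chac1 lost its call (adjusted p = 0.062).

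Of 16 measured interferon response genes, 4 fell and none rose over all genes tested, and 9 fell when adjusted over the list alone. Ifit3 fell by 1.02 ± 0.13, Ifit1 by 0.86 ± 0.11, Usp18 by 0.69 ± 0.12 and Ifih1 by 0.50 ± 0.09, and each of the K289R arrays lay below the WT mean of the list. Isg15, also an interferon-induced gene, differed by -0.06 ± 0.09 (adjusted p = 0.687). This was the 1 list of 34 past the threshold with camera (adjusted p = 0.000302, against adjusted p = 0.979 with an estimated correlation). Other splits of the 14 arrays put up to 14 lists past the threshold. In the list of cytokines, the interferon-induced chemokine gene Cxcl9 fell by 1.29 ± 0.17, Il1rn rose by 0.25 ± 0.07, and the other 14 genes did not pass, with the same counts when adjusted over the list alone. The 4 interferon genes and Cxcl9 also passed with sets as random blocks, and Il1rn did not (adjusted p = 0.0815). The mean of the interferon list differed by -0.30 among replicates 1 to 4 and by -0.31 among replicates 5 to 7.

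Of 14 Kupffer cell and macrophage markers, 4 fell, 1 rose and 9 did not pass. Vsig4 (-0.75 ± 0.12), C1qc (-0.52 ± 0.11) and Folr2 (-0.46 ± 0.10) fell, and C1qa rose by 0.30. The camera adjusted p of the list was 0.353, and adjusted p = 0.979 with an estimated correlation, and the fry adjusted p was 0.469. Of 14 sinusoidal endothelial markers, 5 rose and 1 fell, among them Eng (0.37 ± 0.07) and Fcgr2b (-0.33 ± 0.08). Of 14 stellate cell and fibroblast markers, 2 rose and 1 fell, with Lum lower (-0.60 ± 0.11) and Des higher (0.39 ± 0.10). Cd4 was the 1 gene of 12 T and NK cell markers that rose (0.40 ± 0.10). Among 12 hepatocyte markers Serpinc1 rose (0.12 ± 0.04), a call lost in 10 of 14 fits that left out 1 array. Among 9 adipocyte markers 2 rose and 2 fell, with Fabp4 lower (-0.53 ± 0.08) and Retn higher (0.71 ± 0.13). The others were Pck1 (0.96 ± 0.25), which is in the glucose list too, and Car3 (-0.41 ± 0.06). Their WT means were 9.64 and 12.63, against 5.60 for Fabp4 and 5.57 for Retn. No marker of B and plasma cells (11 measured), neutrophils (10), cholangiocytes (9), exocrine pancreas (15) or erythroid cells (4) passed. When adjusted over the list alone, 6 endothelial markers rose and 2 fell and no hepatocyte marker passed, while the counts of the other cell lists stayed. When sets were random blocks, 3 macrophage markers fell and none rose, 3 endothelial markers rose and 1 fell, Lum alone of the stellate cell markers passed, 1 adipocyte marker rose and 2 fell, Cd4 kept its call, and Serpinc1 lost its call (adjusted p = 0.133).

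In the list of SUMO pathway genes and nuclear receptor cofactors, 2 of 24 rose and 4 fell. The modifier gene Sumo2 (-0.87 ± 0.07), the protease gene Senp5 (-0.38 ± 0.07) and the ligase gene Pias2 (-0.40 ± 0.09) fell, while Prox1, which encodes a corepressor of LRH-1, rose by 0.43 ± 0.10. All 4 probe sets of Sumo2 fell alike, but whether they share probes was not examined, so their agreement is not separate support. Of 18 cell cycle genes 4 fell and none rose, with Ccnd1 at -0.62 ± 0.09 and Mcm6 at -0.41 ± 0.09, while the calls of Mki67 and Top2a were lost in 10 and 5 of 14 fits that left out 1 array. Of 19 xenobiotic metabolism genes 1 rose and 4 fell, with Cyp2c55 at -1.34 ± 0.10 and Cyp2c29 at -0.56 ± 0.06. Of 24 acute phase genes 5 rose and 3 fell, among them Serpina3n (0.45 ± 0.10) and Crp (-0.82 ± 0.08). Of 15 clock genes, Clock fell by 0.34 ± 0.06 and its paralogue Npas2 rose by 0.48 ± 0.11. When adjusted over the list alone, 5 xenobiotic genes fell, and the counts of the other lists in this paragraph stayed. With sets as random blocks 1 SUMO list gene rose and 3 fell, 2 cell cycle genes fell, 1 xenobiotic gene rose and 3 fell, 3 acute phase genes rose and 2 fell, and both clock genes kept their calls. Among replicates 5 to 7 alone the xenobiotic list went down (camera adjusted p = 0.00598, against adjusted p = 0.669 with an estimated correlation).

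Genes of liver zones and of sex gave mixed results. Of 13 pericentral genes 2 rose and 2 fell, with the ammonium transporter gene Rhbg higher (0.76 ± 0.11). Of 10 periportal genes 4 rose and 4 fell, with the urea cycle gene Arg1 lower (-0.43 ± 0.06). Of 11 male-biased genes, Elovl3 rose (0.31 ± 0.05) and Mup20 fell (-0.17 ± 0.06, adjusted p = 0.0485), a call lost in 11 of 14 fits that left out 1 array. Of 8 female-biased genes, Cyp17a1 rose. Of 4 sex-chromosome genes, the Y-linked gene Kdm5d fell by 0.41 ± 0.13, a call lost with median centring (adjusted p = 0.0518) and in 7 of 14 fits that left out 1 array. When adjusted over the list alone, 2 male-biased and 2 sex-chromosome genes fell, and the counts of the other lists stayed. With sets as random blocks 2 pericentral genes rose and 1 fell, 2 periportal genes rose and 4 fell, and Mup20 and Kdm5d lost their calls (adjusted p = 0.184 and 0.083).

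**Figure D3:**
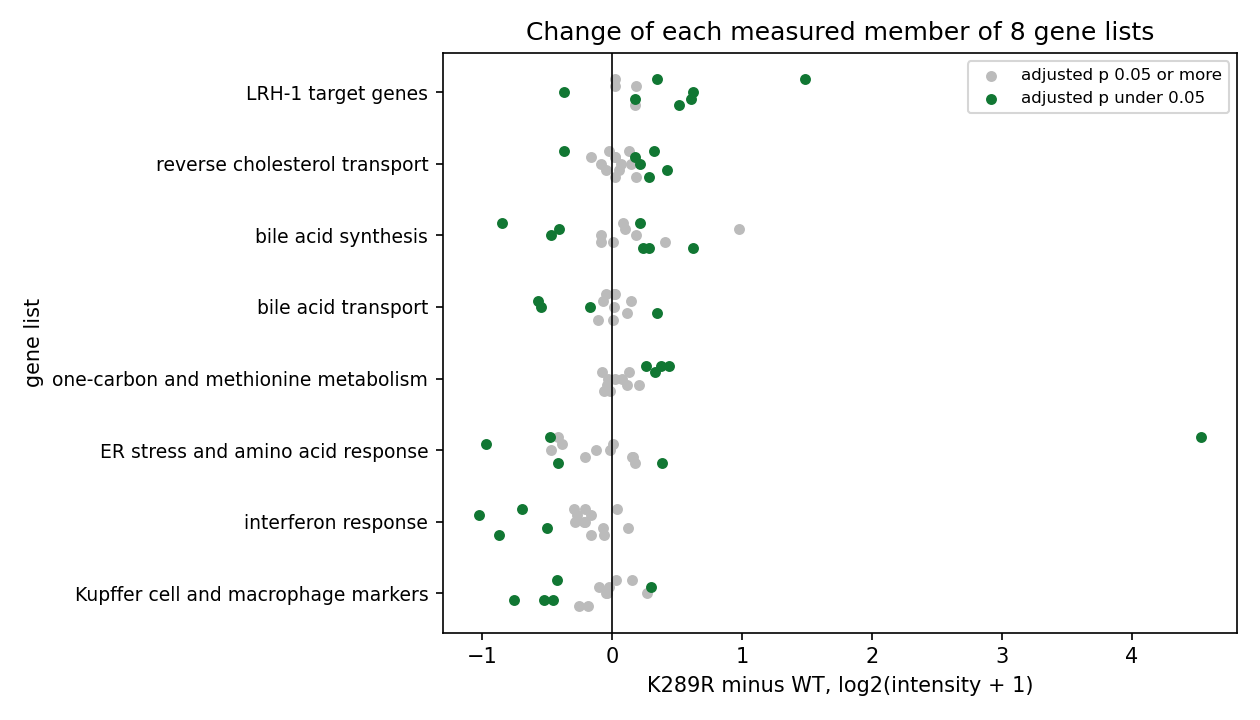
Log2 change, K289R minus WT (x axis), of each measured member of 8 gene lists (y axis), in green where the adjusted p over all genes was under 0.05 and in grey otherwise. Members of the interferon list lie mostly left of 0, members of the LRH-1 target list mostly right of 0, and Asns stands alone at 4.53.

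With fry 6 of 34 lists passed, and its mixed test passed 28 lists, which measures change in either direction. For 12 lists the median, the mean and the camera direction did not share a sign, and the smallest camera adjusted p among these 12 was 0.505. The directions of the LRH-1 target, interferon and one-carbon lists were the same with quantile normalization and with median centring.

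Genes within 20 Mb of Nr5a2 on its chromosome were examined because a knock-in allele can carry flanking DNA. Of 221 such genes 52 passed (23.5%), against 3621 of 18965 others (19.1%), an odds ratio of 1.30 with a 95% confidence interval of 0.93 to 1.79 (Fisher's exact p = 0.102). Ctse is among them. Pm20d1, which encodes an enzyme of N-acyl amino acids, rose by 0.77 ± 0.06, Snrpe by 0.85 ± 0.09 and Insig2, which retains sterol sensors in the endoplasmic reticulum, by 0.57 ± 0.07. Acmsd fell by 0.88 ± 0.10 and Zc3h11a by 0.58 ± 0.07.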

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

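The tests of other splits of the arrays were set before their results were seen. The test of genes near Nr5a2 and camera on the lists, with both correlations, were planned before the data were examined. The remaining tests in this part were chosen after the results were seen.

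The first pattern is the breadth of the difference, 3678 genes. Of 1716 possible splits of the 14 arrays into 7 and 7, 100 were drawn, the real one included. Only the real one gave as many genes, and 3 of the others gave any. The highest other split gave 1357 genes and kept 5 of 7 arrays on the side of their genotype. Splits that kept 6 of 7 gave 0, 378 or 524 genes. This argues against chance division of single arrays as the source of the full count. A division that crosses genotype can still call many genes. With the interquartile range as a covariate 3583 of the genes kept their call and direction, which argues against unequal spread of signal as the source of most calls. The ranges differed little between genotypes (exact permutation p = 0.298), which left this covariate little to remove. The balance of directions did depend on it: 2348 genes were higher and 2171 lower with it, against 1610 and 2068 without. It also turned the camera direction of 10 of 34 lists. Replicates 1 to 4 and 5 to 7 of each genotype form sets, whose origin may be litters, days or a batch, and with the 4 sets as random blocks 2176 of the genes kept their call and direction (consensus correlation 0.178) while 1502 lost it, so that a contribution of the sets stays open. In K289R livers the sets coincide with the spread of signal, with interquartile ranges of 2.28 to 2.49 on replicates 5 to 7 and of 2.61 to 2.70 on replicates 1 to 4. The 2 cannot be told apart there. The labels give no batch, and one that coincides with genotype was not tested.

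The second pattern is the set of genes near Nr5a2 that changed, with Ctse at its head. DNA of another strain around the edited gene could bring expression variants along, and called genes within 20 Mb had an odds ratio of 1.304 (95% confidence interval 0.93 to 1.79). That interval holds both no excess and a clear one. Narrower windows gave no sign of a larger excess, with odds ratios of 1.12 within 10 Mb (95% confidence interval 0.72 to 1.69) and 0.94 within 5 Mb (0.52 to 1.62). For single genes, Ctse, Pm20d1, Snrpe, Insig2, Acmsd and Zc3h11a, flanking DNA cannot be told apart from an effect of the substitution. The labels give no strain, and an effect of LRH-1 on these genes was not tested.

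The third pattern is the fall of 4 of 16 interferon response genes, whose list passed with camera (adjusted p = 0.000302) and was lost at adjusted p = 0.979 with an estimated correlation. For the count of lists, 100 of 100 splits gave at least the 1 list of the real one and the highest other gave 14, so chance cannot be excluded for that count, and the members of the interferon list had an estimated correlation of 0.312, far above the preset 0.01. An exact permutation test of the mean of each list, which needs no such correlation, gave the interferon mean a difference of -0.30 (p = 0.00175, adjusted p = 0.0264 over 34 lists), lower than the WT mean on 7 of 7 K289R arrays. It asks whether a mean differs at all, whereas camera compares a list with other genes. Of 302 gene families grouped by the start of the symbol, 73 passed it too, so it does not set the interferon list apart. Fewer macrophages may contribute: the macrophage mean differed by -0.15 (exact permutation p = 0.161), and the interferon mean by a further -0.1571 (exact permutation p = 0.113), which leaves this open. Unequal spread of signal is argued against as the whole cause, since the median change of the list was -0.1861 with the interquartile range as a covariate and -0.21 without. The limit of that covariate given for the first pattern holds here too.

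Among 270 groups of 7 arrays, 15 had 1 array far from the other 6 by Dixon's ratio of gap to range, where chance flags about 1 in 20 groups, 13.5 here. On K289R replicate 2 these were Serpina3n (0.767) and Itih3 (0.671), both highest, Mylip (0.585, highest) and Cyp2c55 (0.743, lowest). On K289R replicate 5 they were Snrpe (0.662, lowest), Orm1 (0.574, lowest) and Fdps (0.594, highest). On K289R replicate 7 they were Rpl12 (0.577, lowest), Ahcy (0.631, highest) and Insig2 (0.586, highest), and on K289R replicate 6 Pigr (0.704, lowest). On WT arrays they were Fabp7 on replicate 2 (0.591, highest), Npas2 on replicate 4 (0.584, lowest), Pmvk on replicate 5 (0.756, lowest) and Slc1a2 on replicate 7 (0.617, lowest).

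Among the 11724 probe sets with no listed gene, which the comparisons of named genes do not use, 1406 (11.99%, against 18.39% of those with a listed gene) passed limma's adjusted p of 0.05, 514 higher and 892 lower in K289R livers. The excess of lower ones came from the 6617 with identifiers below those of any listed gene (231 higher, 640 lower), and the other 5107 had 283 higher and 252 lower. The strongest were probe sets 10582888 (log2 change 1.58) and 10582916 (1.26) upward, and 10339101 (-1.98) and 10341962 (-1.94) downward. What the unlisted probe sets measure was not given in the sources used here. Whether some are control probe sets stays unknown, so their changes are not read as changes of transcripts.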

How the results depend on the processing

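The tests of list means, the interquartile range as a covariate, the data without a pseudocount, the data without K289R replicates 6 and 7 and the treatments of the sets of replicates 1 to 4 and 5 to 7 were chosen after the data were seen. The count of changed genes was 1762 among replicates 5 to 7 alone and 2176 with sets as random blocks, and lay within 1.5 times of 3678 under the other alternatives, from 2710 among replicates 1 to 4 alone and 2888 with a fold of at least 1.2 to 4665 at an adjusted p of 0.10. It was 4119 with a set term, the 3678 among them, and ran from 3082 to 3857 when 1 array was left out. Without K289R replicates 6 and 7 there were 3418, of which 2950 were shared. Of 118 named genes past the threshold, 68 passed in each of the 17 settings that held them, and none reversed. Filters on dim genes took some named genes out of a setting, and these were not tested there. With sets as random blocks 96 passed, and 12 lost their call in at least 1 of 14 fits that left out 1 array. The count of lists was 2 with array weights, 2 with 1 surrogate variable, 2 with the interquartile range as a covariate, 3 without K289R replicates 6 and 7, 0 with an estimated correlation, 6 with fry, 4 with the exact permutation of list means, 3 among replicates 1 to 4 alone, 3 among replicates 5 to 7 alone, and 1 to 2 when 1 array was left out.

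The difference of Nr5a2, near 0, reversed to 0.069 with quantile normalization, 0.0424 with array weights, 0.086 with 1 surrogate variable, 0.0831 with the interquartile range as a covariate, 0.1181 without K289R replicates 6 and 7 and 0.1206 among replicates 1 to 4 alone. That of Abcg5 reversed to -0.052 with array weights, -0.0482 without those arrays and -0.0156 among replicates 1 to 4 alone, where that of Scarb1 reversed to -0.0121. The odds ratio for genes near Nr5a2 reversed to 0.9445 with a window of 5 Mb. The cause was not tested for any of these.

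Replicate numbers do not pair the arrays. Arrays of the same number correlated from -0.298 to 0.562 in their deviations from the group means, 3 of 7 pairs were above 0.1, and 2 numbers found their own best partner. With the replicate block, 3838 genes passed, 3488 of them shared in the same direction. Dim genes limit the data, since medians of olfactory receptor genes near 3.4 set the level under which a fall cannot be seen.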

Other observations

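The comparison of single genes and camera on the gene lists, with both correlations, were planned before the data were examined. The other tests in this part, camera on gene families among them, were chosen after the data were seen. Genes sharing the start of their symbol were grouped into 302 families of at least 8, and camera put 20 past an adjusted p of 0.05, 19 lower and 1 higher in K289R livers, with none left with an estimated correlation and 4 left with the interquartile range as a covariate. An exact permutation test of family means put 73 past it, 45 lower, and 41 with median centring. The Ugt genes, which conjugate drugs and bilirubin with glucuronic acid, fell in 6 of 11 cases and rose in none, with Ugt2b34 at -0.74 ± 0.05 (log2, SE) and Ugt2b35 at -0.99 ± 0.11, and members of this family can share probes. Of 10 Srsf splicing factor genes 5 fell, with Srsf2 at -1.04 ± 0.07, and of 10 Utp genes of ribosomal RNA processing 6 fell, with Utp18 at -0.80 ± 0.13. Of 12 Hspa heat shock genes 6 fell, with Hspa13 at -0.68 ± 0.11. The family that was higher was that of the lipoprotein receptor relatives, where 5 of 11 Lrp genes rose, with Lrp5 at 0.55 ± 0.06 and Lrp2 at 0.41 ± 0.07. With that covariate the camera calls of the Hspa (adjusted p = 0.0536) and Lrp (adjusted p = 0.0558) families were lost. The direction of each of these families was the same with quantile normalization and median centring.

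Of 23 Snora genes 11 fell and none rose, with Snora44 at -1.01 ± 0.11, and of 29 Snord genes 12 fell and 2 rose, with Snord35b at -1.21 ± 0.15. The Snora mean did not pass the exact permutation test (adjusted p = 0.091), and the Snord mean passed it (adjusted p = 0.0243) but not with median centring (adjusted p = 0.066). With the interquartile range as a covariate the camera call of the Snord family was lost (adjusted p = 0.116). Within families, single members moved apart: Ndufb4 and Ndufb9 of complex I fell by 1.36 and 1.03, while Ndufb7 and Ndufb6 rose by 0.53 and 0.45. Of 49 Rpl genes 17 fell and 8 rose.

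By the exact permutation of list means, 4 lists passed over 34. The LRH-1 target mean was higher by 0.34 in K289R livers (adjusted p = 0.0264) and above the WT mean on each of the 7 K289R arrays, with a list median of 0.19 and Cyp17a1 (1.48) the largest change of its 11 members. The one-carbon mean was higher by 0.13 (adjusted p = 0.0264), with a list median of 0.10. Neither list passed with camera (adjusted p = 0.0708 and 0.353, and for both adjusted p = 0.979 with an estimated correlation). The female-biased mean was higher by 0.35 (adjusted p = 0.0297), with Cyp17a1, which is in the LRH-1 list too, its 1 gene past the threshold and a list median of 0.10, and did not pass with camera (adjusted p = 0.486, and adjusted p = 0.979 with an estimated correlation). Permuted within the sets of replicates 1 to 4 and 5 to 7, the adjusted p was 0.0324 for the interferon, LRH-1 and one-carbon lists and 0.0486 for the female-biased list. That permutation exchanged single arrays between genotypes, as if each set were shared by both. It does not account for 4 separate sets, so these p-values can be too small. With median centring the adjusted p was 0.0462 for the LRH-1 list, 0.42 for the one-carbon list and 0.0743 for the female-biased list, and the cell cycle mean passed as well (-0.12, adjusted p = 0.0462).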
